A study of Arabidopsis thaliana with 24 samples.

How the data were processed

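RNA of 24 rosette pools, 2 for each of 6 genotypes grown in the lab and in the field, was extracted with TRIzol, amplified by in vitro transcription together with 10 spike-in control transcripts and labelled with Cy5 or Cy3, per the labels' protocols. Arrays formed loops within the lab and within the field. Pools numbered 1 formed one loop over all 6 genotypes, and pools numbered 2 formed separate loops of 3 genotypes, so ratios alone do not join all pools. The Cy3 label that reads eds on one lab array was taken as eds1, the one group missing from that loop. The deposited scanner files hold the intensity of each spot as mean pixel intensity and median local background, not normalized, from Agilent Feature Extraction 10.1.1.1, per the file headers. Processed signals in the same files are intensity values from which background was subtracted, with detrending, and which were then dye-normalized (linear and LOWESS), per the file headers. Deposited flags, 0 or 1 per spot, mark spots well above background, saturated spots and outliers, per the file headers. The deposited value table holds log2 of processed Cy5 over processed Cy3. This was checked on 24 of 24 arrays and held within 1e-06. Its array medians ran from -0.239 to 0.186, so it was not centred further. Build ath1 is named in the file headers, and how the authors normalized between arrays is not given in the sources used here.

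Spot intensities were background-corrected with normexp (offset 50), normalized within arrays by loess with control spots at weight 0, and scaled between arrays by Aquantile, in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8). Outlier flags were left out. Spots of one probe were averaged, and both channels of a pool were averaged, which balances the dyes. Of 43803 spots that are not controls, holding 43603 probes, 23543 probes were well above background in all 4 channels of at least 1 group and were kept. The brightest probe stood for a gene, giving 18074 genes, 16981 with a TAIR locus, of which 16837 matched the reference table used for symbols. No genome was used, and coordinates are those of the headers' build. The model had 12 groups, a shared estimate of spread with a trend on intensity (lmFit and eBayes, 12 residual and 4.24 prior degrees of freedom) and no covariate. Comparisons were each mutant against WT and each double mutant against lsd1, in the lab and in the field, the difference of the lsd1 effect between field and lab, an F test of this difference over the 5 mutants, and field against lab in WT and over 6 genotypes. P-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. In this model they measure the spread between pools. Where no channel of a group was well above background, the fold is a lower bound, the bright group's mean against the dim group's mean of the higher of the floor and the probe's own value per array, from normalized log2 values.

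The mapping of samples, the tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. The rule names the 3 mutated genes in every group. For each comparison it adds the 6 genes that rose most and the 6 that fell most, among those past the threshold with no overlap between pools of both groups, which chance gives for many genes at 2 pools per group. For field against lab over 6 genotypes the same sign in all 6 was required instead. From each list it adds up to 4 members past the threshold with the largest change, and members of a list may be named with their values where they did not pass. The text gives a part of the genes so named. The 21 lists cover salicylic acid defence, jasmonate, ethylene, camalexin and indole glucosinolates, aliphatic glucosinolates, antioxidant enzymes, oxidative stress, photosystems, the Calvin-Benson cycle, drought and abscisic acid, cold, flavonoids, heat shock, senescence, cell death, aquaporins, the clock, the mutated genes, and markers of flower, root and seed. Lists were tested with camera at a preset correlation of 0.01, adjusted over 357 tests (21 lists in 17 comparisons). Where a test passed, the p-value with an estimated correlation is given too.

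Alternatives were the processed signals, quantile scaling of all 48 channels, no filter on dim probes, the mean of a gene's probes, a replicate block, a loop fit of ratios, the same fit of the deposited ratios, separate fits of lab and field, slides as fixed effects in a fit of channels with pools as a random block (pool correlation 0.68), and leaving out each pool in turn. Slides as a random block of array means (slide correlation 0.429) applied to field against lab. After the slide pattern was seen, removal of each probe's slide effect before averaging and a fit without slides 2 and 6 were added, as were fits without lsd1 and eds1lsd1. Values with slides fitted come from the fit of channels, and within-slide values compare channels that share a slide. The same channels make up the pool means, so both are weak checks for genes named for a large change. Of all genes past the threshold, at least 99.7% had the same sign within each slide. The steps were tested on simulated data for lsd1 against WT in the lab, over 18074 genes with 50 changed at each size. With slide effects larger than those in these arrays, the model of pool means recovered 0, 0, 44 and 88% of log2 changes of 0.5, 1, 2 and 3, with 0 false calls. The fit with slides as fixed effects recovered 26, 98, 100 and 100%, with 39 false calls, and the loop fit recovered 32, 92, 100 and 100%, with 104 false calls. Without slide effects the model of pool means recovered 10, 94, 100 and 100%, with 8 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.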

Results

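Transcript levels were measured in rosettes of 5-week-old Arabidopsis thaliana of the accession Ws. Wild type (WT), the single mutants lsd1, eds1 and pad4 and the double mutants eds1lsd1 and pad4lsd1 were grown in the laboratory (lab) and in the field. Each of the 12 groups held 2 pools of 3 plants, labelled as separate biological samples. All 24 pools were hybridised once with each dye on 24 dual-colour Agilent arrays, and no array joined a lab pool with a field pool. Between 42.5 and 59.9% of probes were well above background per channel, the median signal per channel was 81.8 to 162, and 0 spots were saturated. Across the 18074 genes tested, which are not independent replicates, pairs of pools correlated at r = 0.773 to 0.998. The number of arrays, with n = 2 pools per group, limits the precision of every comparison. The arrays lay on 6 slides, 1 to 3 holding lab pools and 4 to 6 field pools, and slides 2 and 6 shared a technical pattern (r = 0.877 across 18074 genes). The SD between both channels of a pool had a median of 0.451 across 2 slides and 0.127 within 1 slide (12 pools each). Each pair across slides included slide 2 or 6, so this cannot single them out. Values in brackets after a gene are log2 differences ± limma's SE, or a lower bound of the fold where no channel of a group was well above background. Where the probe had fewer than 4 channels of a group well above background, their number is given. Gene lists carry the adjusted p of camera. Values with slides fitted or within slides stand beside the results for this reason.

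The mutated genes are LSD1 (AT4G20380), a zinc finger protein that restrains cell death, and EDS1 (AT3G48090) and PAD4 (AT3G52430), lipase-like proteins that promote salicylic acid defence. LSD1 signal averaged 9.70 in lab WT and 9.73 in field WT (log2 of normalized intensity, n = 2 pools). It averaged 6.24 in lsd1, 6.31 in eds1lsd1 and 6.35 in pad4lsd1 in the lab, against 7.92, 7.59 and 6.42 in the field. The lab difference from WT was -3.46 ± 0.26 in lsd1, -3.39 ± 0.26 in eds1lsd1 and -3.34 ± 0.26 in pad4lsd1, with adjusted p of at most 1.12e-05 in each. In the field it was -1.81 ± 0.26 in lsd1, -2.14 ± 0.26 in eds1lsd1 and -3.31 ± 0.26 in pad4lsd1. Of 4 channels per group, 2 were well above background in lab lsd1 and 1 each in lab eds1lsd1 and in lab and field pad4lsd1. With processed signals the field lsd1 difference was -2.14 ± 0.70 (adjusted p = 0.196), the call lost to the wider spread. All 3 LSD1 probes, the tested one at chromosome 4, 11006270 to 11006416 (build ath1, as named in the headers), showed this pattern. PAD4 signal (probe at chromosome 3, 19445243 to 19445302) averaged 8.49 in lab WT and 5.999 in lab pad4, and 9.74 and 6.21 in the field. PAD4 was at least 4.67-fold lower in lab pad4 than in WT and at least 10.8-fold lower in field pad4. As fitted, which is not exact, the lab difference was -2.49 ± 0.36, and the call was lost, with a smaller difference and wider spread, at -2.33 ± 0.59 (adjusted p = 0.0553) with slides fitted, -2.33 ± 0.45 (adjusted p = 0.138) without WT lab pool 2 and -2.19 ± 0.43 (adjusted p = 0.166) without pad4 lab pool 2. In pad4lsd1 the signal was 6.01 in the lab and 6.07 in the field. Of the remaining 2 PAD4 probes, both dim, 1 read 6.144 in lab pad4 against 6.511 in WT and 6.118 against 6.832 in the field, and the other 6.71 against 6.675 and 6.425 against 6.495. EDS1 signal (probe at chromosome 3, 17766565 to 17766624) averaged 8.81 in lab WT and 8.66 in lab eds1, and 11.10 and 9.51 in the field. The labels do not say where the eds1 mutation lies, so this probe checks little about the eds1 lines.

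**Figure D1:**
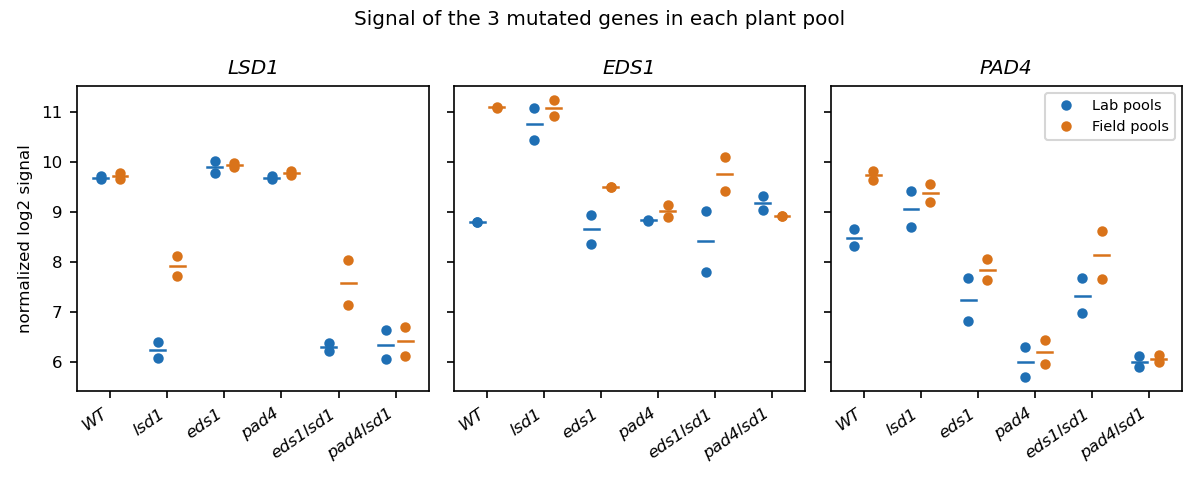
Normalized log2 signal of LSD1, EDS1 and PAD4 in each of the 24 pools, by genotype and by lab or field (points are pools, bars are means of 2 pools). LSD1 averaged 6.24 in lab lsd1 and 7.92 in field lsd1, against 9.70 and 9.73 in WT, and PAD4 averaged 5.999 and 6.21 in pad4.

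The first comparison asked how loss of LSD1 changed the transcriptome of lab plants. Defence, senescence and oxidative stress genes rose and cold genes fell in lsd1 (n = 2 pools per group). Genes that rose most included ABCG40 (an importer of abscisic acid, AT1G15520, 7.33 ± 0.41), NATA1 (an ornithine acetyltransferase, AT2G39030, 6.34 ± 0.41) and AT2G45220 (a pectin methylesterase, 6.08 ± 0.41). Those that fell most included XTH31 (a cell wall xyloglucan enzyme, AT3G44990, -4.38 ± 0.22), ADS1 (a fatty acid desaturase, AT1G06080, -3.63 ± 0.23) and AXR3 (a repressor of auxin responses, AT1G04250, -3.29 ± 0.21). In total 8020 genes (4819 up, 3201 down) passed, 2634 of them by at least 2-fold, against 10945 with slides fitted (7760 shared with the same sign). Of the 8020 genes, 8012, 8020 and 7997 had the same sign within slides 1, 2 and 3. Of 27 salicylic acid defence genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone). The median was 1.48 (1.41 with slides fitted, 1.41 to 1.57 within slides), adjusted p = 2.28e-10, and adjusted p = 0.0998 with an estimated correlation. Members that rose included FMO1 (a flavin monooxygenase needed for systemic acquired resistance, AT1G19250, at least 42.2-fold higher), UGT76B1 (a glucosyltransferase acting on salicylic acid, AT3G11340, at least 27.8-fold higher), PBS3 (an enzyme of salicylic acid synthesis, AT5G13320, 4.002 ± 0.40) and WRKY18 (a transcription factor, AT4G31800, 3.11 ± 0.36). Of 15 camalexin and indole glucosinolate genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 1.31 (1.38 with slides fitted, 1.34 to 2.26 within slides), adjusted p = 1.3e-06, and adjusted p = 0.181 with an estimated correlation. The list held PAD3 (the last enzyme of camalexin synthesis, AT3G26830, 5.54 ± 0.35), CYP79B2 (the entry enzyme of camalexin and indole glucosinolate synthesis, AT4G39950, 3.82 ± 0.28) and ASA1 (anthranilate synthase, AT5G05730, 3.53 ± 0.22). Of 16 ethylene genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone). The median was 1.28 (1.25 with slides fitted, 1.11 to 1.32 within slides), adjusted p = 8.78e-05, and adjusted p = 0.24 with an estimated correlation. Examples were PR3 (a chitinase induced by ethylene, AT3G12500, 4.28 ± 0.36), PR4 (a chitin-binding protein induced by ethylene, AT3G04720, 2.91 ± 0.29) and ACS6 (an ethylene synthesis enzyme, AT4G11280, 2.27 ± 0.41). Of 23 jasmonate genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone). Their median was 1.29 (1.29 with slides fitted, 1.197 to 1.63 within slides), adjusted p = 3.82e-04, and adjusted p = 0.193 with an estimated correlation. They included TAT3 (a jasmonate-induced tyrosine aminotransferase, AT2G24850, 3.83 ± 0.24) and PDF1.2B (a defensin, AT2G26020, 3.66 ± 0.58, 1 of 4 WT lab channels). Of 14 oxidative stress genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone). The median was 1.54 (1.56 with slides fitted, 1.12 to 2.27 within slides), adjusted p = 5.1e-04, and adjusted p = 0.316 with an estimated correlation. Among those that rose were AOX1D (an alternative oxidase of mitochondria, AT1G32350, 4.87 ± 0.35, 1 of 4 WT lab channels), GSTU24 (a glutathione transferase, AT1G17170, 4.79 ± 0.55) and ZAT12 (a zinc finger regulator, AT5G59820, 3.24 ± 0.46). Of 16 senescence genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 1.88 (1.84 with slides fitted, 1.42 to 2.21 within slides), adjusted p = 1.44e-05, and adjusted p = 0.272 with an estimated correlation. Largest here were WRKY75 (a transcription factor that promotes leaf senescence, AT5G13080, 5.28 ± 0.37), SAG29 (a sugar transporter of senescing leaves, AT5G13170, 4.36 ± 0.68) and ASN1 (asparagine synthetase, AT3G47340, 3.94 ± 0.41). Of 18 clock genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 1.04 (0.99 with slides fitted, 0.86 to 1.35 within slides), adjusted p = 4.11e-04, and adjusted p = 0.272 with an estimated correlation. Clock genes that rose included FKF1 (a blue light receptor of the clock, AT1G68050, 2.93 ± 0.27), PRR5 (a pseudo-response regulator, AT5G24470, 2.48 ± 0.19) and PRR3 (a pseudo-response regulator, AT5G60100, 2.298 ± 0.34). Of 14 cell death genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.54 (0.47 with slides fitted, 0.41 to 0.65 within slides), adjusted p = 0.0272, and adjusted p = 0.283 with an estimated correlation. In this list BAP2 (an inhibitor of cell death, AT2G45760, 5.11 ± 0.33, 2 of 4 WT lab channels) and MC8 (a metacaspase, AT1G16420, at least 3.45-fold higher) rose most.

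Cold genes moved the other way in lab lsd1. Of 13 cold response genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone). The median was -2.19 (-2.04 with slides fitted, -2.42 to -1.36 within slides), adjusted p = 6.08e-07, and adjusted p = 0.0587 with an estimated correlation. Among them were GOLS3 (galactinol synthase, AT1G09350, -3.48 ± 0.23), CBF2 (a cold response regulator, AT4G25470, -2.62 ± 0.41) and CBF3 (a cold response regulator, AT4G25480, -2.50 ± 0.28). Of 14 aliphatic glucosinolate genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone). Their median was -0.69 (-0.73 with slides fitted, -1.26 to -0.37 within slides), adjusted p = 0.00214, and adjusted p = 0.459 with an estimated correlation. Both IPMI1 (a subunit of isopropylmalate isomerase, AT3G58990, -1.95 ± 0.38) and IPMI2 (a subunit of isopropylmalate isomerase, AT2G43100, -1.52 ± 0.25) fell. Of 49 photosystem genes, 0 rose and 9 fell (0 and 3 adjusted over the list alone). The median was -0.22 (-0.26 with slides fitted, -0.36 to -0.11 within slides), adjusted p = 0.00232, and adjusted p = 0.658 with an estimated correlation. The fall was large for LHCB4.3 (a light-harvesting protein, AT2G40100, -3.13 ± 0.28). In the flavonoid pathway PAL1 (phenylalanine ammonia lyase, AT2G37040, 2.42 ± 0.29) rose while CHS (chalcone synthase, AT5G13930, -2.05 ± 0.23) and PAP1 (a regulator of anthocyanins, AT1G56650, -1.61 ± 0.29) fell. Of 23 flavonoid genes, 3 rose and 9 fell (3 and 9 adjusted over the list alone). Their median was -0.40 (-0.51 with slides fitted, -0.85 to -0.24 within slides), adjusted p = 0.0133, and adjusted p = 0.276 with an estimated correlation. Heat shock genes showed no joint shift. Of 19 heat shock genes, 4 rose and 1 fell (2 and 1 adjusted over the list alone). The median was 0.026 (0.025 with slides fitted, 0.014 to 0.10 within slides), adjusted p = 0.939. Adjusted p was at most 6.71e-04 among the genes named in this paragraph. With those of the paragraph before, 39 of 39 kept call and sign with slides fitted (largest move 0.21, IPMI1), 39 the same sign within each slide.

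**Figure D2:**
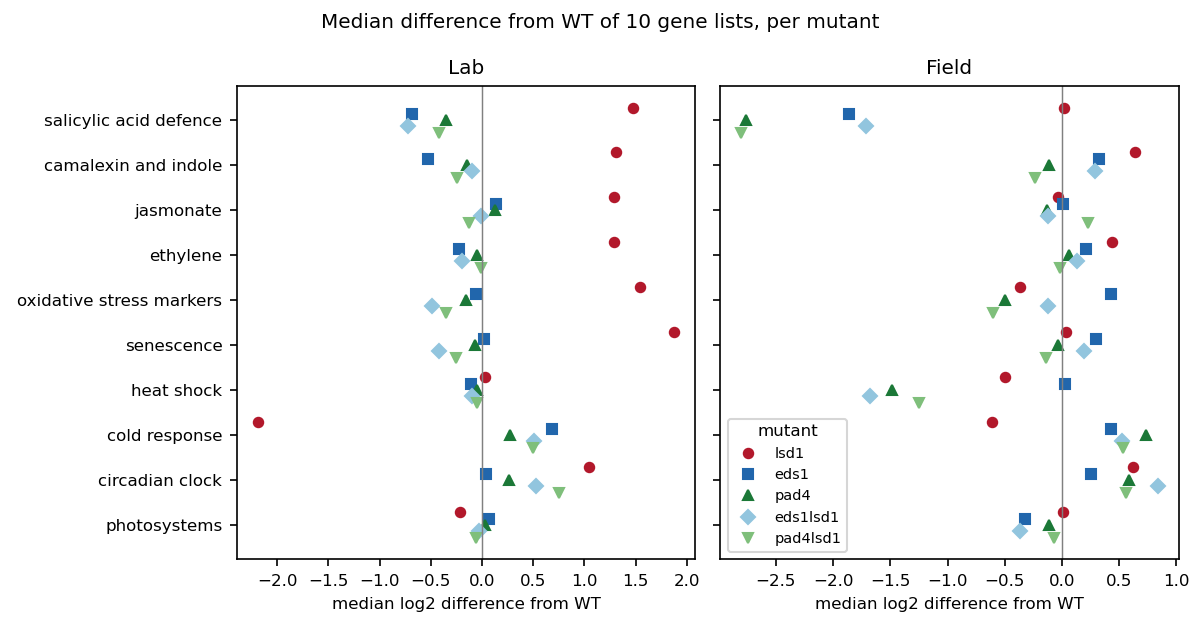
Median log2 difference from WT (horizontal axis) over the genes of 10 lists in each of the 5 mutants, in the lab and in the field. In the lab the salicylic acid defence median was 1.48 in lsd1 and -0.68 in eds1, while in the field it was -2.76 in pad4 and -2.80 in pad4lsd1.

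The single mutants eds1 and pad4 were set against WT in the lab (n = 2 pools per group). In eds1, PR2 (a glucanase induced by salicylic acid, AT3G57260, -2.095 ± 0.23) and TMT1 (a sugar transporter of the tonoplast, AT1G20840, -1.86 ± 0.18) fell, and both calls held with every pool left out in turn. PAP1 (1.66 ± 0.29) rose, but had 1.31 ± 0.33 (adjusted p = 0.365) without WT lab pool 1 and 1.86 ± 0.36 (adjusted p = 0.115) without eds1 lab pool 1. In total 50 genes (30 up, 20 down) passed in eds1, against 3272 with slides fitted (50 shared with the same sign). The eds1 count was 7 without WT lab pool 1, 13 without WT lab pool 2, 11 without eds1 lab pool 1 and 1727 without eds1 lab pool 2. Among the 27 salicylic acid defence genes, 0 rose and 2 fell (0 and 10 adjusted over the list alone). Their median was -0.68 (-0.63 with slides fitted, -0.80 to -0.59 within slides), adjusted p = 5.95e-11, and adjusted p = 0.0924 with an estimated correlation. The genes named for eds1 had adjusted p of at most 0.0228, and 3 of 3 kept call and sign with slides fitted (largest move 0.094, TMT1), 3 the same sign within each slide.

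In lab pad4, genes near the start of chromosome 5 fell, AT5G01350 (-4.69 ± 0.33, 2 of 4 pad4 lab channels), AT5G01015 (-3.67 ± 0.34, 1 of 4 pad4 lab channels) and AT5G01300 (at least 2.85-fold lower), and ALG10 (AT5G02410, 1.33 ± 0.12) from the same stretch rose. PR2 (-1.89 ± 0.23) was lower, as in eds1. The pad4 comparison gave 18 genes (7 up, 11 down), against 94 with slides fitted (16 shared with the same sign). The count was 11 without WT lab pool 1, 8 without WT lab pool 2 and 11 without pad4 lab pool 2. In the salicylic acid defence list, 0 of 27 genes rose and 1 fell (0 and 4 adjusted over the list alone). The median was -0.35 (-0.32 with slides fitted, -0.37 to -0.28 within slides), adjusted p = 1.6e-14, and adjusted p = 0.0594 with an estimated correlation. The pad4 genes named here had adjusted p of at most 7.73e-04. With PAD4 included, 5 of 6 kept call and sign with slides fitted (largest move 0.19, AT5G01350), 6 the same sign within each slide.

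Both double mutants were set against WT in the lab to ask what remained of the lsd1 difference (n = 2 pools per group). In eds1lsd1, AT1G07050 (3.14 ± 0.30), FKF1 (2.67 ± 0.27), LUX (an evening complex factor, AT3G46640, 1.75 ± 0.18) and PRR5 (1.65 ± 0.19) rose. PR2 (-2.90 ± 0.23, 2 of 4 eds1lsd1 lab channels), PR5 (a thaumatin-like protein induced by salicylic acid, AT1G75040, -2.48 ± 0.31), TAT3 (at least 3.57-fold lower) and AT1G24140 (-2.81 ± 0.35) fell. In pad4lsd1, AT1G07050 (2.76 ± 0.30), FKF1 (2.65 ± 0.27), PRR5 (1.77 ± 0.19) and ACA8 (a calcium pump, AT5G57110, 1.70 ± 0.19) rose and PR2 (-2.63 ± 0.23) fell. The test passed for 224 genes (60 up, 164 down) in eds1lsd1, against 2139 with slides fitted (918 up, 1221 down, 220 shared with the same sign). It passed for 89 genes (49 up, 40 down) in pad4lsd1, against 2789 with slides fitted (88 shared with the same sign). Left-out pools moved the eds1lsd1 count to 115 without WT lab pool 1, 39 without WT lab pool 2, 807 without eds1lsd1 lab pool 1 and 375 without eds1lsd1 lab pool 2. They moved the pad4lsd1 count to 23 without WT lab pool 1, 16 without WT lab pool 2, 18 without pad4lsd1 lab pool 1 and 27 without pad4lsd1 lab pool 2. In eds1lsd1 the salicylic acid list shifted down. There 0 of 27 genes rose and 8 fell (0 and 12 adjusted over the list alone). Their median was -0.72 (-0.78 with slides fitted, -0.93 and -0.82 within slides), adjusted p = 4.54e-17, and adjusted p = 0.0462 with an estimated correlation. It shifted down in pad4lsd1 too. There 0 of 27 genes rose and 3 fell (0 and 10 adjusted over the list alone). The median was -0.42 (-0.42 with slides fitted, -0.47 to -0.36 within slides), adjusted p = 4.96e-09, and adjusted p = 0.126 with an estimated correlation. Clock genes shifted up in eds1lsd1. There 5 of 18 rose and 2 fell (9 and 3 adjusted over the list alone). Their median was 0.52 (0.51 with slides fitted, 0.57 and 0.65 within slides), adjusted p = 5.87e-05, and adjusted p = 0.217 with an estimated correlation. Adjusted p was at most 5.86e-04 for the eds1lsd1 genes and 2.57e-04 for the pad4lsd1 genes. Counting LSD1, 9 of 9 kept call and sign with slides fitted (largest move 0.060, FKF1), 9 the same sign within each slide. For pad4lsd1, 6 of 6 kept call and sign with slides fitted (largest move 0.16, FKF1), 6 the same sign within each slide.

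Setting the double mutants against lsd1 asked which lsd1 differences in the lab depended on EDS1 or PAD4. Genes that were high in lab lsd1, defence genes among them, were lower in both (n = 2 pools per group). In eds1lsd1, ABCG40 (-7.61 ± 0.41, 2 of 4 eds1lsd1 lab channels), PAD3 (-7.10 ± 0.35, 1 of 4 eds1lsd1 lab channels), AT2G45220 (-7.00 ± 0.41, 3 of 4 eds1lsd1 lab channels) and NATA1 (-6.25 ± 0.41) fell against lsd1. EDS1 itself was lower, -2.35 ± 0.31. Genes that rose included XTH31 (4.39 ± 0.22), GOLS3 (4.09 ± 0.23) and ADS1 (3.40 ± 0.23). In total 7556 genes (2946 up, 4610 down) passed, against 10437 with slides fitted (7265 shared with the same sign). Without eds1lsd1 lab pool 1 the count was 4957. Among the 27 salicylic acid defence genes, 0 rose and 26 fell (0 and 26 adjusted over the list alone). The median was -2.62 (-2.58 with slides fitted, -2.81 and -2.56 within slides), adjusted p = 1.31e-16, and adjusted p = 0.0487 with an estimated correlation. FMO1 (at least 46.7-fold lower), PR5 (-5.42 ± 0.31) and PBS3 (-4.25 ± 0.40) were among them. Senescence genes fell, with WRKY75 (at least 63.2-fold lower), SAG29 (-5.12 ± 0.68, 2 of 4 eds1lsd1 lab channels) and ASN1 (-4.46 ± 0.41). Among the 16 senescence genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone). Their median was -2.28 (-2.26 with slides fitted, -2.59 and -2.11 within slides), adjusted p = 2.43e-07, and adjusted p = 0.199 with an estimated correlation. Oxidative stress genes fell too, with GSTU24 (-4.99 ± 0.55) and ZAT10 (a zinc finger regulator, AT1G27730, -4.97 ± 0.43). Among the 14 oxidative stress genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone). The median was -2.105 (-2.21 with slides fitted, -2.80 and -2.47 within slides), adjusted p = 2.41e-06, and adjusted p = 0.192 with an estimated correlation. Cold genes such as COR6.6 (a cold-induced protein, AT5G15970, 2.96 ± 0.29) rose. Among the 13 cold response genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 2.29 (2.29 with slides fitted, 2.36 and 2.38 within slides), adjusted p = 3.16e-09, and adjusted p = 0.0308 with an estimated correlation. Named genes had adjusted p of at most 2.78e-05, and 17 of 17 kept call and sign with slides fitted (largest move 0.12, GOLS3), 17 the same sign within each slide.

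Against lsd1, lab pad4lsd1 showed lower ABCG40 (-7.60 ± 0.41, 2 of 4 pad4lsd1 lab channels), NATA1 (-6.87 ± 0.41, 1 of 4 pad4lsd1 lab channels), PAD3 (-6.57 ± 0.35) and AT4G16260 (a glucanase, -6.72 ± 0.38). Levels were higher for XTH31 (4.38 ± 0.22), GOLS3 (4.37 ± 0.23) and ADS1 (3.52 ± 0.23). A total of 6123 genes (2630 up, 3493 down) passed, against 9691 with slides fitted (5933 shared with the same sign). The count was 3816 without lsd1 lab pool 2 and 3696 without pad4lsd1 lab pool 1. Salicylic acid defence genes fell, with FMO1 (at least 49.4-fold lower), PR5 (-4.89 ± 0.31) and PBS3 (-4.03 ± 0.40). In the salicylic acid defence list, 0 of 27 genes rose and 22 fell (0 and 25 adjusted over the list alone). The median was -2.46 (-2.46 with slides fitted, -2.64 to -2.23 within slides), adjusted p = 1.43e-17, and adjusted p = 0.046 with an estimated correlation. Senescence genes such as WRKY75 (at least 59.8-fold lower) and ASN1 (-5.77 ± 0.41) were lower. Here 0 of 16 genes rose and 14 fell (0 and 15 adjusted over the list alone). Their median was -1.85 (-1.92 with slides fitted, -2.27 to -1.36 within slides), adjusted p = 5.6e-09, and adjusted p = 0.167 with an estimated correlation. Cold genes rose, with COR6.6 (2.73 ± 0.29) and RD29A (a marker of drought and cold, AT5G52310, 2.62 ± 0.32). Here 12 of 13 genes rose and 0 fell (13 and 0 adjusted over the list alone). The median was 2.35 (2.38 with slides fitted, 2.12 to 2.44 within slides), adjusted p = 1.48e-09, and adjusted p = 0.0308 with an estimated correlation. Adjusted p was at most 1.61e-05 for these genes, and 14 of 14 kept call and sign with slides fitted (largest move 0.094, COR6.6), 14 the same sign within each slide.

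In the field, lsd1 was compared with WT in the same way, and fewer genes passed than in the lab (n = 2 pools per group). FMO1 (2.57 ± 0.34), AT1G07050 (2.57 ± 0.30), AT5G63225 (2.19 ± 0.23) and GLIP1 (a secreted lipase, AT5G40990, 2.15 ± 0.30) rose. RRTF1 (a redox-responsive transcription factor, AT4G34410, -2.82 ± 0.39, 1 of 4 lsd1 field channels), DDF1 (a relative of the CBF regulators, AT1G12610, -2.84 ± 0.21, 3 of 4 lsd1 field channels), AT1G19210 (-2.85 ± 0.37) and CBF1 (a cold response regulator, AT4G25490, -2.59 ± 0.40) fell. The test passed for 414 genes (188 up, 226 down), 217 of them by at least 2-fold, against 1720 with slides fitted (387 shared with the same sign). The count was 121 without WT field pool 1, 225 without WT field pool 2, 132 without lsd1 field pool 1 and 272 without lsd1 field pool 2. Camalexin and indole glucosinolate genes shifted up, with CYP79B2 (1.85 ± 0.28) and ASA1 (1.73 ± 0.22). Among the 15 listed, 3 rose and 0 fell (6 and 1 adjusted over the list alone). Their median was 0.64 (0.66 with slides fitted, 0.54 to 0.74 within slides), adjusted p = 1.87e-06, and adjusted p = 0.183 with an estimated correlation. Clock genes shifted up as well, with FKF1 (1.78 ± 0.27). Here 7 of 18 genes rose and 1 fell (9 and 3 adjusted over the list alone). The median was 0.62 (0.58 with slides fitted, 0.51 to 0.54 within slides), adjusted p = 2.67e-04, and adjusted p = 0.264 with an estimated correlation. Cold genes shifted down. Among the 13 listed, 0 rose and 4 fell (0 and 4 adjusted over the list alone). Their median was -0.61 (-0.56 with slides fitted, -0.75 to -0.28 within slides), adjusted p = 1.75e-07, and adjusted p = 0.0492 with an estimated correlation. Drought genes shifted down too. Of 14 drought and abscisic acid genes, 0 rose and 2 fell (0 and 7 adjusted over the list alone). The median was -0.64 (-0.61 with slides fitted, -0.71 to -0.62 within slides), adjusted p = 4.41e-09, and adjusted p = 0.0587 with an estimated correlation. Salicylic acid defence showed no joint shift, with WRKY53 (a transcription factor, AT4G23810, -1.80 ± 0.25) lower. Among the 27 listed, 2 rose and 3 fell (4 and 3 adjusted over the list alone). Their median was 0.015 (-0.016 with slides fitted, -0.091 to 0.17 within slides), adjusted p = 0.621. Median and mean lay above 0 there, and the test pointed down. For the named genes adjusted p was at most 0.0015. With LSD1 counted, 13 of 13 kept call and sign with slides fitted (largest move 0.22, RRTF1), 13 the same sign within each slide.

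Salicylic acid defence genes were lower in field eds1 than in WT (n = 2 pools per group). On the lower side stood PCC1 (AT3G22231, -3.50 ± 0.52), AT2G44240 (-3.47 ± 0.21), PCR1 (AT1G14880, -3.41 ± 0.41) and NUDT6 (a Nudix hydrolase, AT2G04450, -3.12 ± 0.34). On the higher side stood RNS1 (a ribonuclease induced by phosphate starvation, AT2G02990, 3.70 ± 0.52), NRT2.1 (a nitrate transporter, AT1G08090, 3.01 ± 0.22), AGP17 (an arabinogalactan protein, AT2G23130, 2.73 ± 0.37) and PAP22 (a purple acid phosphatase, AT3G52820, 2.65 ± 0.31). EDS1 signal was lower too, -1.59 ± 0.31. In total 1208 genes (600 up, 608 down) passed, against 3226 with slides fitted (1126 shared with the same sign). The count was 463 without WT field pool 1, 584 without WT field pool 2 and 491 without eds1 field pool 1. Of 27 salicylic acid defence genes, 0 rose and 22 fell (0 and 25 adjusted over the list alone). The median was -1.86 (-1.88 with slides fitted, -2.12 to -1.26 within slides), adjusted p = 3.13e-34, and adjusted p = 0.0103 with an estimated correlation. Members that fell included ACD6 (an ankyrin protein that promotes salicylic acid defence, AT4G14400, -3.00 ± 0.50) and WRKY70 (a transcription factor downstream of salicylic acid, AT3G56400, -2.93 ± 0.36). The flavonoid list shifted up, with GSTF12 (needed for anthocyanin transport, AT5G17220, 2.27 ± 0.39). Among the 23 flavonoid genes, 7 rose and 0 fell (10 and 1 adjusted over the list alone). Their median was 0.49 (0.51 with slides fitted, 0.34 to 0.44 within slides), adjusted p = 7.57e-06, and adjusted p = 0.0819 with an estimated correlation. The aquaporin list did too, with TIP1;2 (a tonoplast aquaporin, AT3G26520, 1.06 ± 0.19). Of 17 aquaporin genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone). The median was 0.46 (0.45 with slides fitted, 0.44 to 0.58 within slides), adjusted p = 3.71e-05, and adjusted p = 0.166 with an estimated correlation. In the cold list CBF1 (-2.69 ± 0.40) and CBF2 (-2.38 ± 0.41) fell and GOLS3 (1.98 ± 0.23) rose. Adjusted p was at most 0.00449 for the genes named, and 16 of 16 kept call and sign with slides fitted (largest move 0.13, GOLS3), 16 the same sign within each slide.

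Field pad4 also had lower salicylic acid defence genes, with lower heat shock genes (n = 2 pools per group). AT2G44240 (-6.62 ± 0.21), PCR1 (-5.72 ± 0.41, 2 of 4 pad4 field channels), PCC1 (-5.25 ± 0.52) and LURP1 (needed for resistance to downy mildew, AT2G14560, -5.12 ± 0.46) fell. EDS1 was lower as well, -2.07 ± 0.31. NRT2.1 (3.23 ± 0.22), UGT74E2 (a glucosyltransferase induced by hydrogen peroxide, AT1G05680, 2.90 ± 0.38), COR15B (a cold-induced chloroplast protein, AT2G42530, 2.90 ± 0.55) and FKF1 (2.70 ± 0.27) rose. In total 2519 genes (1208 up, 1311 down) passed, against 5184 with slides fitted (2363 shared with the same sign). The count was 1291 without WT field pool 1, 1378 without WT field pool 2, 1463 without pad4 field pool 1 and 1636 without pad4 field pool 2. Among the 27 salicylic acid defence genes, 0 rose and 26 fell (0 and 27 adjusted over the list alone). Their median was -2.76 (-2.83 with slides fitted, -2.82 to -2.32 within slides), adjusted p = 2.44e-34, and adjusted p = 0.0103 with an estimated correlation. Examples were PR1 (a salicylic acid marker, AT2G14610, -4.43 ± 0.32, 2 of 4 pad4 field channels) and NUDT6 (-4.14 ± 0.34). Among the 19 heat shock genes, 0 rose and 14 fell (0 and 15 adjusted over the list alone). The median was -1.48 (-1.55 with slides fitted, -1.93 to -1.05 within slides), adjusted p = 1.79e-13, and adjusted p = 0.0853 with an estimated correlation. They included HSP21 (a chloroplast heat shock protein, AT4G27670, -2.85 ± 0.47), HSP17.6A (a small heat shock protein, AT1G59860, -2.53 ± 0.21) and HSP90.1 (a chaperone, AT5G52640, -2.51 ± 0.33). The clock list shifted up, with GRP7 (a clock-controlled RNA-binding protein, AT2G21660, 1.77 ± 0.30) and LUX (1.74 ± 0.18). Rises passed for 9 of 18 clock genes and falls for 0 (9 and 1 adjusted over the list alone). Their median was 0.58 (0.58 with slides fitted, 0.58 to 0.73 within slides), adjusted p = 1.5e-05, and adjusted p = 0.183 with an estimated correlation. The cell death list shifted down, with MC8 (-1.92 ± 0.15) lower and LOL1 (a relative of LSD1 that promotes cell death, AT1G32540, 0.76 ± 0.14) higher. Among the 14 cell death genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone). The median was -0.43 (-0.44 with slides fitted, -0.56 to -0.18 within slides), adjusted p = 0.00275, and adjusted p = 0.176 with an estimated correlation. FSD1 (iron superoxide dismutase, AT4G25100, -3.84 ± 0.28), TAT3 (-2.93 ± 0.24) and ACS6 (-2.19 ± 0.41) fell. Between eds1 and WT and between pad4 and WT, 382 genes rose in both and 559 fell in both. Independent lists would share 40.1 and 44.1. The WT pools enter both sides and can add to the overlap. The covariance of the differences was 0.179, against a mean of 0.0274 in 20 simulations of unchanged groups, which held no slide effects. No gene named here had an adjusted p above 0.00158. With PAD4 counted, 22 of 22 kept call and sign with slides fitted (largest move 0.28, COR15B), 22 the same sign within each slide.

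The double mutants in the field were also set against WT (n = 2 pools per group). In eds1lsd1, AT1G07050 (3.82 ± 0.30), AT5G42730 (3.17 ± 0.24), FKF1 (3.11 ± 0.27) and ELF4 (an evening complex factor, AT2G40080, 2.86 ± 0.48) rose. ZAT7 (a zinc finger protein, AT3G46090, -3.90 ± 0.27), PCR1 (-3.15 ± 0.41), NAC090 (a NAC transcription factor, AT5G22380, -3.08 ± 0.24) and NUDT6 (-2.96 ± 0.34) fell. In total 1566 genes (678 up, 888 down) passed, against 4234 with slides fitted (1488 shared with the same sign). The count was 590 without WT field pool 1, 761 without WT field pool 2 and 954 without eds1lsd1 field pool 1. Heat shock genes fell, with HSP17.6A (-2.56 ± 0.21) and MBF1C (a co-activator of heat responses, AT3G24500, -2.33 ± 0.22). Here 0 of 19 genes rose and 17 fell (0 and 17 adjusted over the list alone). Their median was -1.67 (-1.70 with slides fitted, -1.83 and -1.81 within slides), adjusted p = 1.4e-22, and adjusted p = 0.0324 with an estimated correlation. Salicylic acid defence fell as a list, with PR1 (-2.58 ± 0.32). Here 0 of 27 genes rose and 24 fell (0 and 25 adjusted over the list alone). The median was -1.71 (-1.72 with slides fitted, -1.54 and -1.87 within slides), adjusted p = 6.78e-31, and adjusted p = 0.0113 with an estimated correlation. The cell death list shifted down, with MC8 (-1.88 ± 0.15) and BI1 (an inhibitor of cell death, AT5G47120, -0.81 ± 0.16) lower. Here 0 of 14 genes rose and 4 fell (0 and 6 adjusted over the list alone). Their median was -0.33 (-0.33 with slides fitted, -0.28 and -0.40 within slides), adjusted p = 1.56e-04, and adjusted p = 0.0969 with an estimated correlation. Without eds1lsd1 field pool 2, the difference was -4 for PCR1, -3.75 for NUDT6 and -3.18 for PR1. Within slide 5, which held pool 2, it was -2.29, -2.15 and -2.37. The largest adjusted p of these genes was 0.00418. With LSD1 counted, 14 of 14 kept call and sign with slides fitted (largest move 0.10, PR1), 14 the same sign within each slide.

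In field pad4lsd1, AT2G44240 (-6.55 ± 0.21), PCR1 (-5.77 ± 0.41), PCC1 (-5.75 ± 0.52) and LURP1 (-4.78 ± 0.46) fell against WT. EDS1 was lower, -2.18 ± 0.31. AT1G07050 (2.87 ± 0.30), AT5G02760 (2.73 ± 0.35) and KDR (AT1G26945, 2.59 ± 0.26) rose. A total of 1992 genes (875 up, 1117 down) passed, against 4264 with slides fitted (1905 shared with the same sign). The count was 930 without WT field pool 1, 1098 without WT field pool 2, 1232 without pad4lsd1 field pool 1 and 1082 without pad4lsd1 field pool 2. Rises passed for 0 of 27 salicylic acid defence genes and falls for 26 (0 and 27 adjusted over the list alone). The median was -2.80 (-2.83 with slides fitted, -2.94 to -2.65 within slides), adjusted p = 2.18e-45, and adjusted p = 0.00774 with an estimated correlation. They included NUDT6 (-4.49 ± 0.34) and WRKY70 (-4.40 ± 0.36). Heat shock genes were lower, with HSP21 (-2.92 ± 0.47) and HSP17.6A (-1.86 ± 0.21). Rises passed for 0 of 19 heat shock genes and falls for 17 (0 and 18 adjusted over the list alone). Their median was -1.25 (-1.35 with slides fitted, -1.83 to -0.85 within slides), adjusted p = 8.04e-16, and adjusted p = 0.0639 with an estimated correlation. The pad4lsd1 genes had adjusted p of at most 5.23e-04. With LSD1 and PAD4 counted, 13 of 13 kept call and sign with slides fitted (largest move 0.14, AT5G02760), 13 the same sign within each slide.

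Field double mutants were then set against field lsd1 (n = 2 pools per group). LSD1 signal was 7.92 in lsd1, 7.59 in eds1lsd1 and 6.42 in pad4lsd1, so differences in pad4lsd1 need not reflect PAD4 alone. In eds1lsd1, FMO1 (-4.64 ± 0.34), AT5G63225 (-3.90 ± 0.23), BAP2 (-3.61 ± 0.33) and BG3 (a glucanase, AT3G57240, -2.85 ± 0.47) fell and SPX3 (a phosphate signalling protein, AT2G45130, 2.54 ± 0.29) and PAP14 (a purple acid phosphatase, AT2G46880, 2.40 ± 0.28) rose. In pad4lsd1, AT2G44240 (-6.24 ± 0.21), FMO1 (-5.77 ± 0.34, 3 of 4 pad4lsd1 field channels), PCC1 (-5.57 ± 0.52) and PCR1 (-5.37 ± 0.41) fell and IAA1 (an auxin-induced repressor, AT4G14560, 2.04 ± 0.31), KDR (2.00 ± 0.26) and NRT2.1 (1.95 ± 0.22) rose. The test passed for 1005 genes (405 up, 600 down) in eds1lsd1, against 3134 with slides fitted (1646 up, 1488 down, 965 shared with the same sign). It passed for 1396 genes (550 up, 846 down) in pad4lsd1, against 3578 with slides fitted (1831 up, 1747 down, 1342 shared with the same sign). The eds1lsd1 count was 280 without lsd1 field pool 1 and 396 without eds1lsd1 field pool 1. The pad4lsd1 count was 529 without lsd1 field pool 1, 764 without pad4lsd1 field pool 1 and 779 without pad4lsd1 field pool 2. In eds1lsd1 the salicylic acid list fell, with EDS5 (a chloroplast transporter needed for salicylic acid synthesis, AT4G39030, -2.81 ± 0.26) and PR1 (-2.43 ± 0.32). Of 27 salicylic acid defence genes, 0 rose and 21 fell (0 and 24 adjusted over the list alone). The median was -1.68 (-1.74 with slides fitted, -1.36 and -2.01 within slides), adjusted p = 1.59e-32, and adjusted p = 0.0103 with an estimated correlation. In pad4lsd1 it fell with LURP1 (-4.81 ± 0.46) and DLO1 (a salicylic acid hydroxylase, AT4G10500, -4.08 ± 0.23). Among its 27 genes, 0 rose and 24 fell (0 and 26 adjusted over the list alone). Their median was -3.16 (-3.17 with slides fitted, -3.08 to -2.64 within slides), adjusted p = 2.46e-49, and adjusted p = 0.00774 with an estimated correlation. The flavonoid list shifted up in eds1lsd1. There 9 of 23 genes rose and 0 fell (14 and 0 adjusted over the list alone). The median was 0.77 (0.74 with slides fitted, 0.53 and 0.91 within slides), adjusted p = 9.87e-12, and adjusted p = 0.0168 with an estimated correlation. It shifted up in pad4lsd1 too. There 5 of 23 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 0.62 (0.60 with slides fitted, 0.41 to 0.81 within slides), adjusted p = 3.07e-09, and adjusted p = 0.0308 with an estimated correlation. The heat shock list shifted down in pad4lsd1, with HSP21 (-2.67 ± 0.47). Of 19 heat shock genes, 0 rose and 8 fell (0 and 14 adjusted over the list alone). The median was -0.98 (-0.93 with slides fitted, -1.24 to -0.64 within slides), adjusted p = 1.24e-11, and adjusted p = 0.102 with an estimated correlation. Camalexin genes such as CYP79B2 (-1.81 ± 0.28) and MYB51 (a regulator of indole glucosinolates, AT1G18570, -1.27 ± 0.20) fell in pad4lsd1. In the camalexin and indole glucosinolate list, 0 of 15 genes rose and 5 fell (0 and 7 adjusted over the list alone). Their median was -0.78 (-0.74 with slides fitted, -0.84 to -0.77 within slides), adjusted p = 1.94e-06, and adjusted p = 0.183 with an estimated correlation. Adjusted p was at most 0.00148 in eds1lsd1 and 0.00147 in pad4lsd1. Without eds1lsd1 field pool 2, FMO1 had -5.30, BG3 -3.55 and PR1 -3.031. Within slide 5, which held pool 2, they had -3.92, -2.06 and -1.61. For eds1lsd1, 8 of 8 kept call and sign with slides fitted (largest move 0.12, PR1), 8 the same sign within each slide. For pad4lsd1, 12 of 12 kept call and sign with slides fitted (largest move 0.084, PCC1), 12 the same sign within each slide.

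**Figure D3:**
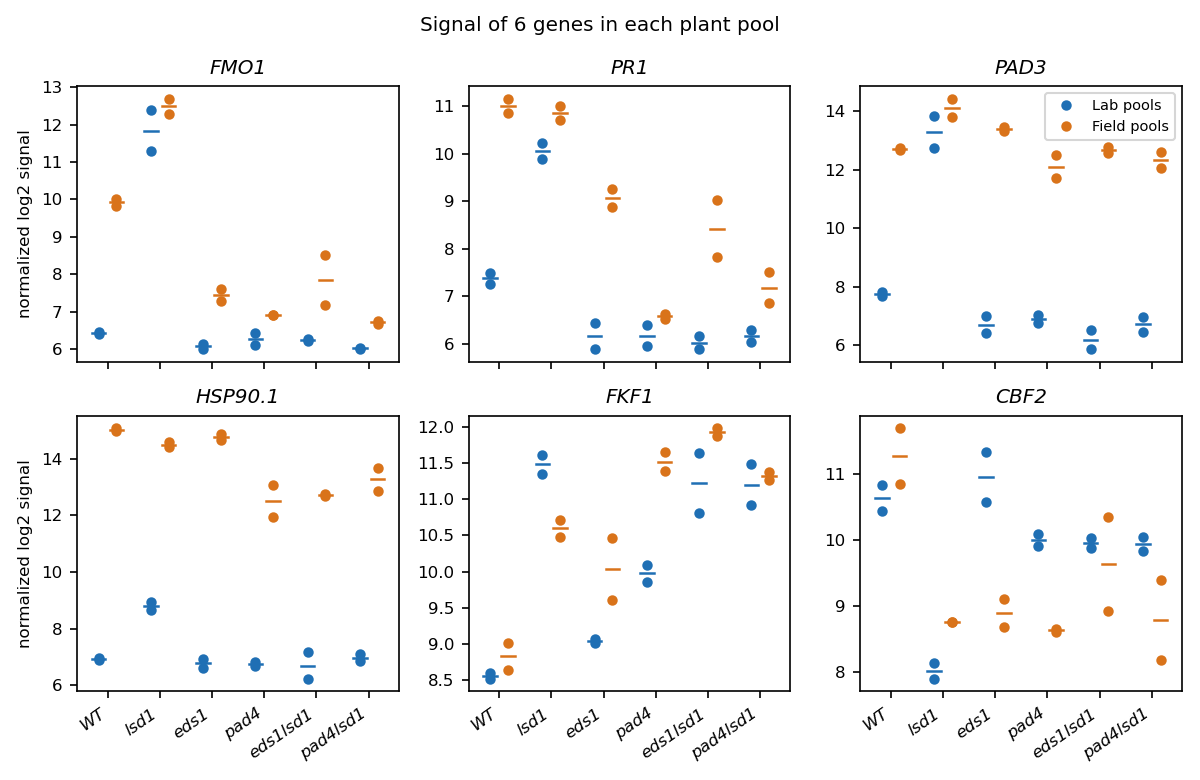
Normalized log2 signal of FMO1, PR1, PAD3, HSP90.1, FKF1 and CBF2 in each of the 24 pools (points), by genotype and by lab or field. HSP90.1 differed by 8.10 ± 0.33 (SE) between field and lab WT.

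A change of the lsd1 difference from WT was tested as an interaction, field minus lab (n = 2 pools in each of the 4 groups). It was positive for XTH31 (3.93 ± 0.31), ADS1 (3.75 ± 0.32), LHCB4.3 (3.23 ± 0.39) and GOLS3 (3.19 ± 0.33, 3 of 4 lsd1 field channels), which were low in lab lsd1. It was negative for LEA7 (a late embryogenesis abundant protein, AT1G52690, -6.41 ± 0.88, 2 of 4 WT lab channels), ABCG40 (-5.41 ± 0.58), SAG29 (-5.39 ± 0.96) and WRKY40 (a transcription factor, AT1G80840, -5.14 ± 0.48). In total 4027 genes (1454 up, 2573 down) passed, against 8279 with slides fitted (3889 shared with the same sign). The count was 2631 without WT lab pool 1, 2440 without WT lab pool 2, 2018 without WT field pool 1 and 2135 without lsd1 field pool 2. Of 27 salicylic acid defence genes, 0 had a positive and 18 a negative interaction (0 and 19 adjusted over the list alone). The median was -1.63 (-1.65 with slides fitted), adjusted p = 7.67e-12, and adjusted p = 0.0853 with an estimated correlation. Among them were WRKY46 (a transcription factor, AT2G46400, -4.24 ± 0.38) and PBS3 (-3.56 ± 0.56). Senescence genes had a negative median, with WRKY75 (-4.15 ± 0.53) and ASN1 (-3.65 ± 0.58). Their median was -1.53 (-1.51 with slides fitted), adjusted p = 3.63e-06, and adjusted p = 0.25 with an estimated correlation. Oxidative stress genes did too, with ZAT12 (-4.65 ± 0.65) and GSTU24 (-3.72 ± 0.78). The median was -1.91 (-1.95 with slides fitted), adjusted p = 6.29e-06, and adjusted p = 0.207 with an estimated correlation. Jasmonate genes followed, with TAT3 (-3.13 ± 0.34) and JAZ1 (a repressor of jasmonate signalling, AT1G19180, -3.50 ± 0.78). Their median was -1.69 (-1.68 with slides fitted), adjusted p = 1.37e-04, and adjusted p = 0.175 with an estimated correlation. Camalexin genes included PAD3 (-4.11 ± 0.49). The median was -0.99 (-1.02 with slides fitted), adjusted p = 1.96e-04, and adjusted p = 0.282 with an estimated correlation. EDS1 (-1.97 ± 0.44) had a negative and LSD1 (1.64 ± 0.37, 2 of 4 lsd1 lab channels) a positive value. Adjusted p was at most 0.0056 here. Of all genes named for this test, 23 of 23 kept call and sign with slides fitted (largest move 0.17, JAZ1). An F test of the change in any of the 5 mutant differences passed for 4827 genes, for 11094 with slides fitted and for 2723 without lsd1 field pool 2.

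In WT, field plants had higher heat shock, salicylic acid defence and jasmonate genes than lab plants (n = 2 pools per group). HSP90.1 (8.10 ± 0.33), HSP23.6 (a small heat shock protein, AT4G25200, at least 171-fold higher), LTP4 (a lipid transfer protein, AT5G59310, 6.92 ± 0.47) and AT2G44240 (7.36 ± 0.21) rose in the field. AT5G48490 (-5.46 ± 0.18), ADS1 (-5.22 ± 0.23), AT5G02760 (-5.15 ± 0.35) and ESM1 (a modifier of glucosinolate breakdown, AT3G14210, -4.72 ± 0.62) fell. A total of 9492 genes (5108 up, 4384 down) passed, 3939 of them by at least 2-fold, against 11828 with slides fitted (9158 shared with the same sign). No slide or scan held both lab and field arrays, so scan and slide sets cannot be told apart from growth condition. Slides fitted here take up differences among lab slides and among field slides only. Among the 19 heat shock genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone). Their median was 4.33 (4.36 with slides fitted), adjusted p = 2.34e-13, and adjusted p = 0.0858 with an estimated correlation. They included HSP17.8 (a small heat shock protein, AT1G07400, 6.83 ± 0.40) and HSP70-4 (a chaperone, AT3G12580, 6.73 ± 0.31). Rises passed for 25 of 27 salicylic acid defence genes and falls for 0 (25 and 0 adjusted over the list alone). The median was 2.098 (2.08 with slides fitted), adjusted p = 3.48e-11, and adjusted p = 0.0886 with an estimated correlation. Examples were WRKY46 (4.74 ± 0.27), PR1 (3.63 ± 0.32) and PBS3 (3.55 ± 0.40). Jasmonate genes rose, with VSP1 (a vegetative storage protein, AT5G24780, 5.82 ± 0.39), VSP2 (a vegetative storage protein, AT5G24770, 5.26 ± 0.39) and TAT3 (4.58 ± 0.24). Among the 23 jasmonate genes, 17 rose and 3 fell (17 and 3 adjusted over the list alone). Their median was 2.43 (2.43 with slides fitted), adjusted p = 3.24e-06, and adjusted p = 0.102 with an estimated correlation. Floral organ genes rose as well, with PI (a floral organ identity factor, AT5G20240, 2.42 ± 0.21), SEP2 (a floral organ identity factor, AT3G02310, at least 2.64-fold higher) and AP3 (a floral organ identity factor, AT3G54340, at least 2.3-fold higher). Of 7 floral organ genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). The median was 1.31 (1.34 with slides fitted), adjusted p = 6.73e-04, and adjusted p = 0.183 with an estimated correlation. EDS1 signal was higher, 2.29 ± 0.31. The photosystem list shifted down, with LHCB2.3 (a light-harvesting protein, AT3G27690, -4.24 ± 0.49) and PSAH2 (a photosystem subunit, AT1G52230, -2.12 ± 0.30). Among the 49 photosystem genes, 3 rose and 23 fell (3 and 23 adjusted over the list alone). Their median was -0.40 (-0.38 with slides fitted), adjusted p = 0.00109, and adjusted p = 0.611 with an estimated correlation. The highest adjusted p of the named genes was 2.06e-05, and 22 of 22 kept call and sign with slides fitted (largest move 0.10, HSP17.8).

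Over all 6 genotypes, 12 field pools were set against 12 lab pools. PS2 (a pyrophosphatase induced by phosphate starvation, AT1G73010, 6.81 ± 0.12), LTP4 (6.64 ± 0.19) and ELIP1 (an early light-induced protein, AT3G22840, 6.63 ± 0.14) rose, with the same sign in every genotype. AT5G48490 (-4.99 ± 0.075, 21 of 24 field channels), LHCB2.3 (-4.29 ± 0.20) and ESM1 (-4.09 ± 0.26) fell in every genotype. In total 14021 genes (7255 up, 6766 down) passed, and 10535 with slides as a random block of array means. Flavonoid genes rose, with CHS (3.51 ± 0.10), PAL1 (3.21 ± 0.12) and PAP1 (2.90 ± 0.12). Of 23 flavonoid genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone). The median was 1.69, adjusted p = 1.83e-07, and adjusted p = 0.0492 with an estimated correlation. Heat shock genes rose, with HSP90.1 (6.64 ± 0.13, 23 of 24 lab channels) and HSP70-4 (5.93 ± 0.13). In the heat shock list, 19 of 19 genes rose and 0 fell (19 and 0 adjusted over the list alone). Their median was 3.54, adjusted p = 3.41e-09, and adjusted p = 0.15 with an estimated correlation. Clock genes such as CCA1 (a morning clock factor, AT2G46830, 2.196 ± 0.10) and PRR3 (1.59 ± 0.14) rose. Of 18 clock genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone). The median was 0.66, adjusted p = 0.00102, and adjusted p = 0.301 with an estimated correlation. Antioxidant enzymes went both ways, with CSD1 (copper-zinc superoxide dismutase, AT1G08830, 3.45 ± 0.11) and CCS (its copper chaperone, AT1G12520, 2.85 ± 0.13) up. Of 28 antioxidant enzyme genes, 14 rose and 13 fell (14 and 13 adjusted over the list alone). Their median was 0.29, adjusted p = 0.55. Of 2 root genes tested, 1 rose, NRT2.1, with 0 of 24 lab and 24 of 24 field channels well above background, and 0 of 9 genes for seed storage proteins and oleosins were bright enough to be tested. Adjusted p of the genes with printed differences was at most 1.6e-08. With slides as a random block, which cannot move a difference in this balanced design, 15 of 15 of these genes kept their call.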

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

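The tests of LSD1 signal, of mixed RNA and of genes that moved away from the lsd1 level in WT were chosen after the results were seen. The test of genes whose level in WT moved little was planned.

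The lsd1 effect differed between field and lab by the interaction test for 4027 genes, and any mutant effect differed by the F test for 4827 genes. Positive differences were XTH31 (3.93 ± 0.31), ADS1 (3.75 ± 0.32), AT5G18030 (3.33 ± 0.54), LHCB4.3 (3.23 ± 0.39), GOLS3 (3.19 ± 0.33, 3 of 4 lsd1 field channels) and AT3G55240 (3.17 ± 0.47). Negative ones were LEA7 (-6.41 ± 0.88, 2 of 4 WT lab channels), AT3G46080 (-5.54 ± 0.56), ABCG40 (-5.41 ± 0.58), SAG29 (-5.39 ± 0.96) and WRKY40 (-5.14 ± 0.48). AT2G38240 had -5.43 as fitted, which is not exact, since 0 of 4 WT lab channels were well above background. Among the mutated genes, EDS1 had -1.97 and LSD1 had 1.64. List medians of the difference were -1.63 for salicylic acid defence, -1.69 for jasmonate, -0.99 for ethylene, -0.99 for camalexin and indole glucosinolates, -1.91 for oxidative stress, -1.02 for drought and abscisic acid, -1.53 for senescence, -0.58 for cell death and -0.66 for the clock. They were 0.75 for aliphatic glucosinolates, 0.23 for photosystems and 1.28 for cold. With an estimated correlation, adjusted p was 0.0853 for salicylic acid defence and 0.175 to 0.66 for the other 11 of these lists.

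LSD1 signal was higher in the field than in the lab in lsd1 (log2 1.68 ± 0.26) and in eds1lsd1 (1.28 ± 0.26). More transcript from the mutant allele in the field would raise it in pad4lsd1 too, where the difference was 0.066 ± 0.262 (limma's SE, 95% interval -0.49 to 0.62), which argues against this as the whole cause. RNA of plants with LSD1 may have entered the pools. A probe at chromosome 5, 5804982 to 5805041, was 7.09 and 7.25 in the lab pools of eds1lsd1 and 9.19 to 10.98 in every other lab pool, and the eds1lsd1 field pools read 7.37 and 8.31. Pool 2 needed 22.7% of other RNA by this probe and 22.3% by LSD1, values that mixing needs there and that could have differed. Pool 1 needed 2.71% by this probe and 7.44% by LSD1, a share at which the probe would read 7.65 in place of 7.37. These lie within 2 residual SD (0.223 each) of one another, so mixing in pool 1 is left open. For lsd1, which needed 15.8 and 24.1% by LSD1, no such probe was used, so mixing there and a mislabelled plant stay open.

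The lsd1 effect was smaller in the field. Over 2633 genes changed at least 2-fold in the lab, LSD1 itself left out, the median effect was 1.36, and with 19.9% of other RNA, the mean share LSD1 needs, a median of 1.09 would remain in the field. The observed median was 0.15 (0.02 to 0.28 over the 4 pairings of pools), which argues against mixed RNA as the whole cause. A level in WT that the field had already brought to that of the mutant is another explanation. Over all 2633 genes the field moved WT by a median of 1.03 (log2) in the direction of the lsd1 effect. For 1973 of them, picked because WT moved this way by at least 0.5 log2, the median effect was 1.39 in the lab and 0.116 in the field (-0.015 to 0.251). That choice itself lowers the field value, so the explanation stays open for these genes. For 510 genes that moved by under 0.5 log2 in WT the median effect was 1.21 in the lab and 0.22 in the field (0.11 to 0.35), and for 150 that moved the other way it was 1.42 and 0.367 (0.21 to 0.49), which argues against it as the whole cause. A biological change of the lsd1 effect with growth condition, which the design names, remains a hypothesis. With slides fitted, 3889 of the 4027 genes with an interaction kept call and sign, while the scans and slide sets that separated lab from field were not tested.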

How the results depend on the processing

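Removing slide effects, leaving out slides 2 and 6 and leaving out lsd1 and eds1lsd1 were chosen after seeing the data, the others planned. Of 252 gene results named, part of those under the rule, 249 kept direction and call under every alternative, left-out pools included. The exceptions, with the direction kept, were LSD1 in field lsd1 with processed signals, PAD4 in lab pad4 with slides fitted or without pool 2 of WT or pad4, and PAP1 in lab eds1 with lab and field fitted separately or without pool 1 of WT or eds1. Of 4053 gene values under alternatives, 4046 kept direction and side of the threshold, 7 lost the call and 0 reversed. Of 192 counts under alternatives other than leaving out a pool, 122 lay within 1.5 times the reported count and 70 did not.

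With the replicate number as a block, 18 of 18 counts stayed within 1.5 times (8091 for lsd1 in the lab, 63 for eds1 in the lab) and 252 of 252 gene results kept their call. Deviations of pools with the same number correlated at -0.71 to 0.76 in the lab and -0.64 to 0.71 in the field, above 0.1 in 7 of 15 pairs of groups in each. With slide effects removed they correlated at -0.048 to 0.48 in the lab, above 0.1 in 9 of 15 pairs, and at -0.013 to 0.59 in the field, above 0.1 in 14 of 15. Not every pair did so, thus the numbers were not taken to pair the samples, though a deviation shared by many same-numbered pools remains.

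Counts that moved by more than 1.5 times follow. With slides as fixed effects the count was 3272 for eds1, 94 for pad4, 2139 for eds1lsd1 and 2789 for pad4lsd1 against WT in the lab, 9691 for pad4lsd1 against lsd1 in the lab, 1720 for lsd1, 3226 for eds1, 5184 for pad4, 4234 for eds1lsd1 and 4264 for pad4lsd1 against WT in the field, 3134 for eds1lsd1 and 3578 for pad4lsd1 against lsd1 in the field, and 8279 for the interaction and 11094 for the F test. Slide effects removed before averaging gave 436 for eds1, 684 for eds1lsd1 and 696 for pad4lsd1 against WT in the lab, 779 for lsd1, 3952 for pad4, 2915 for eds1lsd1 and 3055 for pad4lsd1 against WT in the field, 2041 for eds1lsd1 and 2325 for pad4lsd1 against lsd1 in the field, and 6962 for the interaction and 9162 for the F test. Without slides 2 and 6, which takes out eds1lsd1 pool 1 of both conditions, there were 1084 for eds1, 879 for eds1lsd1 and 1177 for pad4lsd1 against WT in the lab, 694 for lsd1 and 3996 for pad4 against WT in the field, 2321 for pad4lsd1 against lsd1 in the field, and 6745 for the interaction and 8438 for the F test. The loop fit of ratios gave 7253 for eds1, 133 for pad4, 3250 for eds1lsd1 and 4088 for pad4lsd1 against WT in the lab, 12370 for eds1lsd1 and 11048 for pad4lsd1 against lsd1 in the lab, 2377 for lsd1, 5555 for eds1, 7124 for pad4, 6648 for eds1lsd1 and 5931 for pad4lsd1 against WT in the field, 4102 for eds1lsd1 and 5347 for pad4lsd1 against lsd1 in the field, and 8993 for the interaction and 14340 for the F test. The same fit of the deposited table gave 8094 for eds1, 202 for pad4, 3159 for eds1lsd1 and 4287 for pad4lsd1 against WT in the lab, 12309 for eds1lsd1 and 11239 for pad4lsd1 against lsd1 in the lab, 2268 for lsd1, 6518 for eds1, 7224 for pad4, 6378 for eds1lsd1 and 6070 for pad4lsd1 against WT in the field, 4044 for eds1lsd1 and 5669 for pad4lsd1 against lsd1 in the field, and 9145 for the interaction and 14404 for the F test. Fitting lab and field separately gave 4 for eds1, 11 for pad4, 89 for eds1lsd1 and 26 for pad4lsd1 against WT in the lab. Processed signals gave 153 for pad4lsd1 against WT in the lab. Without the filter on dim probes there were 30 for eds1 against WT in the lab. Over 3 mutants the count was 2000 for the F test. Of 180 list tests passing with the preset correlation, 23 passed with an estimated one. Pool means treat the slide difference as spread between pools. The simulations with slide effects, which were larger than those here, bear on the gap to fits with slides, whose false calls they also counted. The cause of the other shifts was not tested.

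In the deposited table, genes higher made up 48.1% (reported 60.1%) for lsd1, 44.0% (reported 60.0%) for eds1 and 44.6% (reported 26.8%) for eds1lsd1 against WT in the lab, 51.7% (reported 39.0%) for eds1lsd1 and 54.3% (reported 43.0%) for pad4lsd1 against lsd1 in the lab, 54.5% (reported 43.9%) for pad4lsd1 against WT in the field, 53.8% (reported 40.3%) for eds1lsd1 and 54.9% (reported 39.4%) for pad4lsd1 against lsd1 in the field, and 50.9% (reported 36.1%) for the interaction. With processed signals they made up 46.0% (reported 60.0%) for eds1 against WT in the lab.

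With each pool left out in turn, where a lone pool is taken to vary like the pools of other groups, counts ran from 5577 to 6633 for lsd1, 7 to 1727 for eds1, 8 to 12 for pad4, 39 to 807 for eds1lsd1 and 16 to 27 for pad4lsd1 against WT in the lab, 4957 to 8914 for eds1lsd1 and 3696 to 5535 for pad4lsd1 against lsd1 in the lab, 121 to 272 for lsd1, 463 to 1046 for eds1, 1291 to 1636 for pad4, 590 to 1075 for eds1lsd1 and 930 to 1232 for pad4lsd1 against WT in the field, 280 to 913 for eds1lsd1 and 529 to 1113 for pad4lsd1 against lsd1 in the field, and 2018 to 3875 for the interaction, 2723 to 6875 for the F test, 7277 to 7662 for field against lab in WT and 13700 to 14405 for field against lab over 6 genotypes. Signal over background limits the rest: genes dim in all groups were not tested. In simulations with slide effects larger than here, where few genes changed, the model of pool means found 0% of log2 changes of 1.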

Other observations

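Tests on chromosome 5 and the overlaps here were chosen after the results were seen. The count over other splits was planned.

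Of the 4819 genes that rose in lab lsd1, 3914 fell in eds1lsd1 and 3111 in pad4lsd1 against lsd1. Of the 3201 genes that fell, 2387 and 2149 rose there, so that 78.6 and 65.6% of the lab lsd1 genes went the opposite way, and 7 and 2 went the same way. Independent lists would share 1229 and 522 genes with eds1lsd1 and 931 and 466 with pad4lsd1. The lsd1 pools enter both sides, which can add to the overlaps. The covariance of the differences, counted positive where they oppose, was 0.614 and 0.552, against means of 0.0272 and 0.0271 in 20 simulations of unchanged groups, which held no slide effects. In the field, 470 genes rose and 722 fell against WT in both eds1lsd1 and pad4lsd1, where independent lists would share 32.8 and 54.9, with 1 gene going opposite ways. There the WT pools are shared, and the covariance was 0.183, against 0.0272 in the simulations.

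With no pool in common, 129 genes that rose in lab lsd1 also rose in field lsd1 and 41 fell in both, where independent lists would share 50.1 and 40, and 58 went opposite ways. The move from lab to field in eds1, pad4, eds1lsd1 and pad4lsd1 also shares no pool with lab lsd1. There 3101, 2684, 2762 and 1932 genes rose in both, against 1512, 1264, 1431 and 1073 in independent lists. Falls in both were 2175, 1710, 1626 and 1261, against 892, 778, 789 and 713, and 496, 544, 741 and 849 genes went opposite ways. Growth condition lay on separate slides and scans in these comparisons.

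Of genes past the threshold between pad4 and WT in the lab, 7 of 17 with a position lay in the first 1 Mb of chromosome 5, which holds 211 of 17828 tested genes with a position. In 10000 random draws of 17 genes at most 4 fell in any window of 1 Mb (permutation p = 1e-04, the smallest these draws can give), which argues against chance placement. Slide differences are argued against as well, since 7 of 7 kept sign and call with slides fitted. For loss of PAD4 as the cause, 5 of the 5 genes that fell (AT5G01015, AT5G01300, AT5G01350, AT5G02080 and UNE18) were lower in pad4 than in pad4lsd1 in both conditions, which argues against it, while 0 of the 2 that rose (ALG10 and AT5G02460) differed there, so loss of PAD4 stays open for them. In eds1, 10 of 48 such genes lay in this window. With pad4 it shared 4, among them ALG10 (1.16) and AT5G02460 (1.325), whose rise there needed no pad4 mutation. A stretch of another accession around these genes in the mutant lines is a candidate explanation that was not tested.

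Other splits of the 24 pools into 12 and 12 were counted for field against lab over 6 genotypes. The real split called 13562 genes in a fit of this factor alone. Of 100 splits, 1, the real one, called as many, and the highest other 6548. Chance is unlikely (1 in 100), though scans and slides follow this split.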
